A study of Xenopus laevis with 17 samples.

How the data were processed

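Gene expression was measured in brains of premetamorphic Xenopus laevis tadpoles, an African frog sampled before its own thyroid hormone rises. Per the labels' protocols, tadpoles were kept for 4 days with DMSO solvent, with 1 nM T3 (triiodothyronine, the active thyroid hormone), or with 1 nM T3 and 500 nM of a hydroxylated polychlorinated biphenyl. Total RNA was extracted, labelled with Cy3 and hybridised to 1-colour Agilent arrays, so each array carried 1 RNA sample. The series holds 17 arrays, of which 5 were DMSO, 6 T3, 3 T3+4OHPCB159 and 3 T3+4OHPCB106.

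Per the submitters' processing notes, the authors read the arrays with Agilent Feature Extraction 9.5.3.1. The processed signal used here is, per the file headers, a spot intensity on a linear scale from which background had been subtracted. The authors also deposited a series table of processed log2 values. Differences between arrays in that table had a slope of 1 on log2 differences of the scanner intensities scaled by the 75th percentile over all probes, with correlations across probes of 0.9845 to 0.9994. Its values were centred per probe, and the baseline subtracted from each probe correlated at 0.9986 with the median over the arrays. Its column medians ran from -0.236 in T3+4OHPCB106 replicate 2 to 0.19 in DMSO replicate 3. How that baseline was computed is not given in the sources used here, and the table served as an alternative only.

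Each array held 44407 spots, of which 1417 were controls and were left out. The 21495 probes were printed as 2 spots each. Spots marked as outliers (96 over all arrays) were left out, and no probe was saturated. The spots of a probe were averaged, and values were taken as log2 of the processed signal minus the array's 75th percentile. Because 43.8% to 46.9% of probes were well above background on an array, the percentile was taken over the 8569 probes well above background on all arrays. The percentile lay between 685.2 and 1035 signal units. Both spots of 1 probe were lost on 1 array, and that value was set to the mean of the other arrays of its group. A probe was tested if it was well above background on at least 3 of the 17 arrays, which 10507 probes were. The standard deviation between spots of one probe on one array was 0.0535 to 0.0861 on the log2 scale. The number of arrays limits the precision.

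Probes were named through the accessions of the array design, looked up in a RefSeq gene table of the organism (6615 probes), by a gene name or synonym of that table (207) or by the array design's own gene name (264), which can be old. Of the 21495 probes, 14359 had no gene name, and 5890 of the tested probes had a symbol that could be named here. The endings .L and .S mark the paired copies of a gene that Xenopus laevis carries. Where a symbol had several probes, the probe with the highest mean over all arrays stood for it, which left 5851 genes.

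Before groups were averaged, arrays of one group were compared with their own spot noise over 4303 bright probes. For 8 pairs of arrays the variance between arrays was below that of repeated spots, with ratios of 0.419 to 0.846. These were DMSO 4 with 5, T3 5 with 6, and all 3 arrays of each compound group. They differed by less than the sampling noise and were averaged and counted as 1 sample, which gave 4 DMSO, 5 T3, 1 T3+4OHPCB159 and 1 T3+4OHPCB106 samples. Other pairs within a group had ratios of 1.38 to 29.1. The design written before the data were examined counted each of the 17 arrays as a sample. The averaging was decided after the counts of that 17-array analysis had been seen, and those counts are printed beside each main result. The lone compound samples were assumed to vary like the DMSO and T3 samples. The labels do not say whether the arrays came from separate animals, tanks or extractions, so p-values measure only the spread between these samples, which may be technical.

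The arrays lay on 5 slides. Slide 1 held DMSO 1 and 2 with T3 1 and 2, slide 2 held T3 3 with the 3 T3+4OHPCB159 arrays, slide 3 held DMSO 3 to 5 with T3 4, slide 4 held T3 5 and 6, and slide 5 held the 3 T3+4OHPCB106 arrays alone. T3 and DMSO were therefore also compared within slides 1 and 3 and with slide as a block, and T3+4OHPCB159 with T3 within slide 2. No slide holds T3+4OHPCB106 and another group, so slide 5 and that treatment cannot be told apart. Within a group the arrays also fell into sets: DMSO 1 and 2 against 3 to 5 (ratios of 15.7 to 29.1 to spot noise) and T3 1 to 3 against 4 to 6 (10.3 to 18.4).

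Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 7 residual degrees of freedom), with all groups sharing 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over the 10507 probes of a comparison, at a threshold of 0.05. Differences are given on the log2 scale as first minus second group, with the standard error (SE) of the fit. A probe that was below background on all arrays of a group has only a bound there. A probe well above background on some arrays of a group keeps its difference and SE, which then rest partly on background values. Its fold is given as at least the brighter group's mean over the dimmer group's mean, with the dim value of each array raised to the lowest signal among probes well above background. Where that bound is under 1 or both groups were below background, no fold is given. The 27 gene lists were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members are said to have risen or fallen when their own limma adjusted p was under 0.05 over all probes. For some lists, counts adjusted over the list alone are given beside these.

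Genes were named by a rule fixed in advance: the 10 largest rises and falls among named genes past the threshold with every array of the first group on one side of the other group's mean, up to 4 members of each list with the smallest p, and thrb, klf9, thibz, dio3, mmp11 and cyp1a genes whatever their values. Where under 5 named genes passed, the 5 highest and lowest of the 20 with the smallest p are given as values. For the compounds against DMSO only counts, lists and the always-named genes are given. Some genes that the rule names are not reported here.

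Whether a compound weakened or strengthened the T3 response was tested by the median of compound minus T3, signed by the direction of T3 minus DMSO, over the probes past the threshold for T3. The selection was repeated in each of the 6 relabellings of 5 T3 samples and 1 compound sample, because T3 samples enter both the selection and the comparison. A score, the mean over the members of the thyroid hormone response list, was compared by exact permutation tests. The same scripts were tested on simulated data with 200 changed probes of 10507. At a log2 change of 1 they recovered 82% for T3 against DMSO, 44% for T3+4OHPCB159 against T3, 41.5% for T3+4OHPCB106 against T3 and 6.5% between the compounds. At a log2 change of 2 they recovered 96%, 83.5%, 86% and 73.5% in the same order. With no change simulated they made no calls. Differences between sets alone were simulated, with no group effect, at the size seen between the 2 T3 sets and drawn separately for each probe. They gave a median of 601.5, 133, 124.5 and 66.5 calls in that order over 20 draws. The fit treats the samples of a set as independent. The DMSO sets differed more (ratios of 15.7 to 29.1 against 10.3 to 18.4), and shared shifts of many probes were not simulated. These counts are therefore no estimate of the calls that the real sets would give.

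Alternatives fixed before the data were examined were quantile normalization, normexp background correction with offset 50, centring on the median, other filters on dim probes, the series table, eBayes with trend and robust settings, replicate number as a block, slide as a fixed or random block, other thresholds, fits of the compared groups alone, and leaving out each array. Added afterwards were each array as a sample, 6 samples made by averaging the sets, the percentile over all probes, fits without DMSO 1 and 2, and fits within slides 1 and 3.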

Results

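Brain transcripts of premetamorphic Xenopus laevis tadpoles were measured after 4 days with DMSO, 1 nM T3, or 1 nM T3 together with 500 nM of either hydroxylated polychlorinated biphenyl, 4OHPCB159 or 4OHPCB106. Such compounds are metabolites of industrial biphenyls and share a phenolic ring with thyroid hormone, and the series asked whether they alter gene expression induced by the hormone. The 17 arrays gave 4 DMSO, 5 T3, 1 T3+4OHPCB159 and 1 T3+4OHPCB106 samples, because arrays that differed by less than the sampling noise between spots were averaged and counted as 1 sample. That step was taken after the counts with every array as a sample had been seen, and both counts are given. Between 43.8% and 46.9% of the 21495 probes were well above background on an array, and 10507 probes were tested. The variance between arrays, relative to spot noise, was 0.419 to 0.484 among the T3+4OHPCB159 arrays and 0.522 to 0.762 among the T3+4OHPCB106 arrays. It was 19.3 to 86 between DMSO and T3 arrays. It was 2.75 to 5.29 between the T3+4OHPCB159 arrays and T3 1 to 3, and 9.14 to 14 against T3 4 to 6. For the T3+4OHPCB106 arrays it was 12.1 to 17.6 against T3 1 to 3, and 7.7 to 15.3 against T3 4 to 6.

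**Figure D1:**
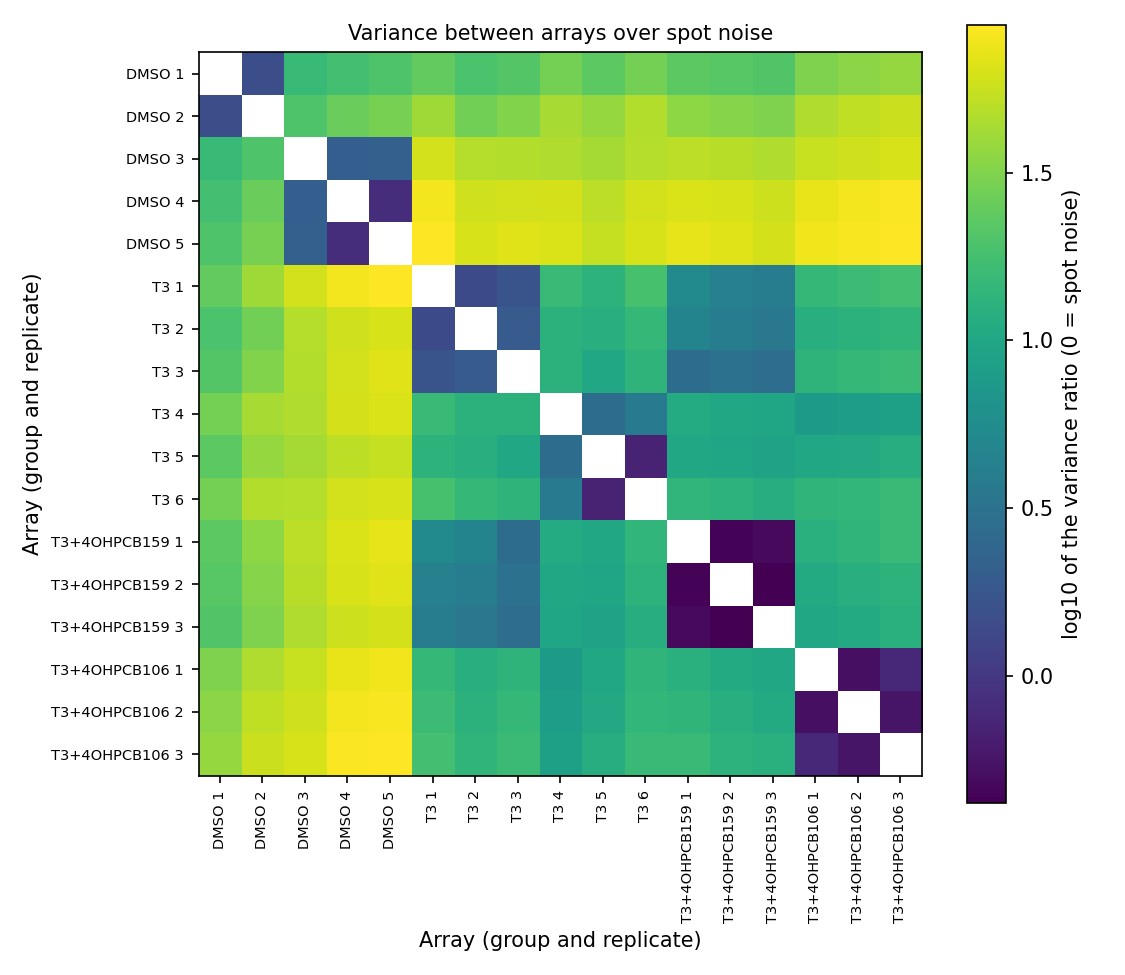
Each cell gives, on a log10 colour scale, the variance between 2 arrays divided by the variance expected from repeated spots, with arrays named by group and replicate on both axes and 0 marking spot noise. The 3 arrays of each compound group differ by less than spot noise, with ratios of 0.419 to 0.762, whereas the DMSO arrays form sets that differ by 15.7 to 29.1 and the T3 arrays sets that differ by 10.3 to 18.4.

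T3 raised direct targets of its receptor in tadpole brain. The thyroid hormone receptor gene thrb rose by 1.85 (SE 0.175, adjusted p = 0.000203 by limma, n = 5 T3 and 4 DMSO samples), and klf9.L, a hormone-induced transcription factor, was at least 3.25-fold higher (adjusted p = 0.000892), being below background in DMSO. In DMSO, thrb and fap.L were well above background on 1 of 5 arrays and mmp11.L on 4, so their rises rest partly on background values. The matrix metalloproteinase gene mmp11.L rose by 2.37 (SE 0.508), mmp13l.S was at least 7.85-fold higher, and the cell surface protease gene fap.L rose by 1.49 (SE 0.136). The rise of thrb was 1.83 within slide 1 and 1.60 within slide 3, that of mmp11.L 1.15 and 3.69, and that of fap.L 1.37 and 1.78. The deiodinase dio3.S, which inactivates thyroid hormone, differed by 0.0558 (95% interval -0.269 to 0.381, adjusted p = 0.784), while dio1.L, another deiodinase, fell by 1.42 (SE 0.234). The probes for dio3.L, thibz.L and cyp1a1.L were well above background on 0 of 17 arrays and were not tested.

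Of the 14 tested members of the list of genes that thyroid hormone is known to induce in tadpoles, 6 rose, 5 fell and 3 did not pass, the same 6 and 5 when adjusted over the list alone. Members that fell included ccn2.L, a matricellular growth factor (fell by 1.23, SE 0.121), crhbp.S, the corticotropin-releasing hormone binding protein (fell by 0.742, SE 0.0833), and mmp9.1.S, which was at least 1.48-fold lower and below background in T3. The list's median was 0.0628 and its mean 0.456, and camera found no shift against other genes (adjusted p = 0.802). The mean of the list per sample was 0.174 in T3 and -0.282 in DMSO, a difference of 0.456 (95% interval 0.257 to 0.656; exact permutation p = 0.00794, the smallest possible, adjusted p = 0.0397 over 5 comparisons). It was 0.292 within slide 1, 0.601 within slide 3 and 0.415 with slide as a block. The mean takes klf9.L, below background in DMSO, and mmp9.1.S, below background in T3, at their measured signal. The sizes of these score differences therefore rest partly on background values.

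Genes of DNA replication and mitosis rose together. Of 78 tested cell cycle members 64 rose and 0 fell by limma, and 68 rose and 0 fell when adjusted over the list alone or at an unadjusted p under 0.05. The median was 1.49, and 75 of the 78 were higher. The largest rises among all named genes included the replicative helicase subunit mcm7.S (3.74, SE 0.671), the spindle protein gene hmmr.L (3.75, SE 0.764), the mitotic kinesins kif23.S (3.71, SE 0.826) and kif20a.L (3.28, SE 0.666), the ribonucleotide reductase subunit rrm2.2.L (3.55, SE 0.649), the topoisomerase top2a.L (3.42, SE 0.705) and thymidylate synthase tyms.L (3.33, SE 0.607). In DMSO, hmmr.L and kif23.S were well above background on 2 of 5 arrays and tyms.L on 3, so the sizes of their rises rest partly on background values. The kinesin copy kif20a.S was at least 5.67-fold higher and the tubulin tuba8 at least 4.49-fold higher, both below background in DMSO. The steadiest rises in the list were tpx2.L (2.40, SE 0.249), kif2c.S (1.76, SE 0.147), mcm10.L (1.67, SE 0.173) and ccna1.S (1.43, SE 0.147). The size differed by slide: the list median was 0.996 within slide 1 and 1.91 within slide 3, and mcm7.S differed by 2.02 and 5.57. It was 1.42 with slide as a block and 0.798 with normexp, which compresses dim probes. Camera gave an adjusted p of 1.05e-15, and an adjusted p of 0.443 with an estimated correlation.

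Sterol synthesis, protein folding, proteasome and respiratory chain genes also rose. In the sterol and fatty acid list 19 of 26 members rose and 3 fell (20 and 3 adjusted over the list alone; median 0.852, 0.644 within slide 1 and 1.07 within slide 3), among them ACAT2 (2.60, SE 0.3), nsdhl.L (1.48, SE 0.191) and acly.S (0.893, SE 0.114). In the heat shock and unfolded protein list 20 of 34 rose and 2 fell (20 and 2 over the list alone; median 0.467, 0.299 and 0.619 by slide), led by creld2.S (1.76, SE 0.165), hsph1.S (1.44, SE 0.186), the disulfide isomerase pdia6.S (1.18, SE 0.0927) and dnaja1.L (0.639, SE 0.0778). Of 24 proteasome subunits 18 rose and 1 fell (19 and 1 over the list alone; median 0.565, 0.416 and 0.748 by slide), as psmc1.L (1.06, SE 0.14) and psmd6.L (0.908, SE 0.084) show. In the respiratory chain list 20 of 31 rose and 1 fell (23 and 2 over the list alone; median 0.356, 0.259 and 0.426 by slide), with ndufs1.L up by 0.732 (SE 0.0741) and atp5f1c.S by 0.628 (SE 0.0723). The exception was the uncoupling carrier ucp2.S, which fell by 2.62 (SE 0.566). Camera gave adjusted p of 0.000151, 0.000513, 3.25e-05 and 3.25e-05 for these lists in order, and an adjusted p of 0.443 for each with an estimated correlation.

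Leukocyte and antigen-processing genes fell. Of 15 immune members 11 fell and 0 rose by limma, also when adjusted over the list alone or at an unadjusted p under 0.05, with a median of -1 (-0.819 within slide 1 and -1.21 within slide 3). The peptide transporter tap2.L, well above background on 3 of 6 T3 arrays, fell by 3.72 (SE 0.885), the immunoproteasome subunit psmb8.L by 2.84 (SE 0.512), the invariant chain cd74.L by 1.49 (SE 0.258), the myeloid transcription factor irf8.L by 1.05 (SE 0.182) and the complement gene c1qb.L by 0.806 (SE 0.145). Interferon and acute phase genes that fell included irf1.L, which fell by 1.01 (SE 0.13), irf1.S, cfb.L and c4a.L. That list as a whole did not pass, with 5 of 15 members down and 0 up by limma, also at an unadjusted p under 0.05 and over the list alone (median -0.0565, camera adjusted p = 0.408). For the immune list camera gave an adjusted p of 0.002, and an adjusted p of 0.465 with an estimated correlation.

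Oligodendrocyte, ribosomal, immediate early and epithelial genes were lower as groups. In the myelin list 8 of 13 members fell and 1 rose, also when adjusted over the list alone (median -0.473, -0.448 within slide 1 and -0.56 within slide 3). It was -0.293 with normexp. The genes included the oligodendrocyte transcription factor sox10.L (fell by 0.81, SE 0.0898) and nkx2-2.S (fell by 0.49, SE 0.111). Of 18 ribosomal protein genes 12 fell and 0 rose by limma (15 and 0 over the list alone or at an unadjusted p under 0.05), with a median of -0.341, which was -0.484 within slide 1 and -0.0912 within slide 3, and -0.164 with quantile normalization or normexp. Among immediate early genes 10 of 20 fell and 3 rose (11 and 3 over the list alone; median -0.367, -0.285 and -0.249 by slide), led by the antiproliferative gene btg1.L (fell by 0.849, SE 0.0785) and nr4a1.S (fell by 0.771, SE 0.0918). Among epithelial markers, a cell type that can be dissected with the brain, 9 of 17 fell and 1 rose (10 and 1 over the list alone; median -0.48, -0.582 and -0.532 by slide, -0.219 with normexp), for example the keratin krt12.5.S (fell by 1.82, SE 0.339) and pkp3.S (fell by 0.963, SE 0.139). Camera adjusted p were 0.0258, 0.00062, 0.029 and 0.029 in order, and the adjusted p with an estimated correlation were 0.42, 0.465, 0.443 and 0.42. The epithelial call ended without DMSO replicate 2 (adjusted p = 0.0502), and the immediate early call with the arrays averaged to 6 sets (adjusted p = 0.0563).

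Other brain genes belonged to lists that did not pass camera. The mature neuron list was lower by fry, which does not compare a list with other genes (adjusted p = 0.00572). The neural progenitor markers nes.S and hes1.S were at least 1.23-fold and 1.44-fold higher, whereas the astroglial enzymes glul.S (fell by 1.84, SE 0.166) and aldh1l1.L (fell by 1.75, SE 0.211) were lower; of 26 members of that list 7 rose and 5 fell. The adhesion molecule ncam1.L rose by 1.09 (SE 0.115) and the neurogenic factor neurod4.L was at least 2.32-fold higher, with 9 of 32 differentiation genes up and 5 down. Among 29 mature neuron genes 2 rose and 9 fell, including the synaptic genes snap25.S (fell by 0.956, SE 0.12) and syt1.L (fell by 1.16, SE 0.11). The Hedgehog-binding protein hhip.L fell by 1.76 (SE 0.191), and pituitary growth hormone Gh fell by 0.912 (SE 0.191), by 1.40 within slide 1 and 0.483 within slide 3. The 10 largest falls also held mogat2.1.L (fell by 2.93, SE 0.438), g6pc1.3.L, a glucose-6-phosphatase gene (fell by 2.68, SE 0.242), and nppa.L (fell by 2.43, SE 0.439; well above background on 4 of 6 T3 arrays). They held rdh7.L, il13ra2.S, tmprss2.3.L and tmem184a.S, which were at least 2.36-fold, 2.59-fold, 2.53-fold and 1.71-fold lower and below background in T3. Of the cell types that could come with the dissection, none of the lists for muscle, cartilage, red cells, photoreceptors, pituitary or choroid plexus and vessels passed camera (lowest adjusted p = 0.258).

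Over all probes T3 raised 1966 and lowered 2279 of 10507 (limma, adjusted p under 0.05), and 2844 and 3237 when every array was counted as a sample. Across all 10507 probes the changes within slides 1 and 3 correlated at r = 0.628, where genes are not independent replicates, and 2077 probes differed between these slides by limma. Averaging the sets to 2 DMSO and 2 T3 samples left 0 calls by limma, with 1905 probes at an unadjusted p under 0.05. Simulated set differences of the size between the T3 sets gave 601.5 calls, and the DMSO sets differed more.

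**Figure D2:**
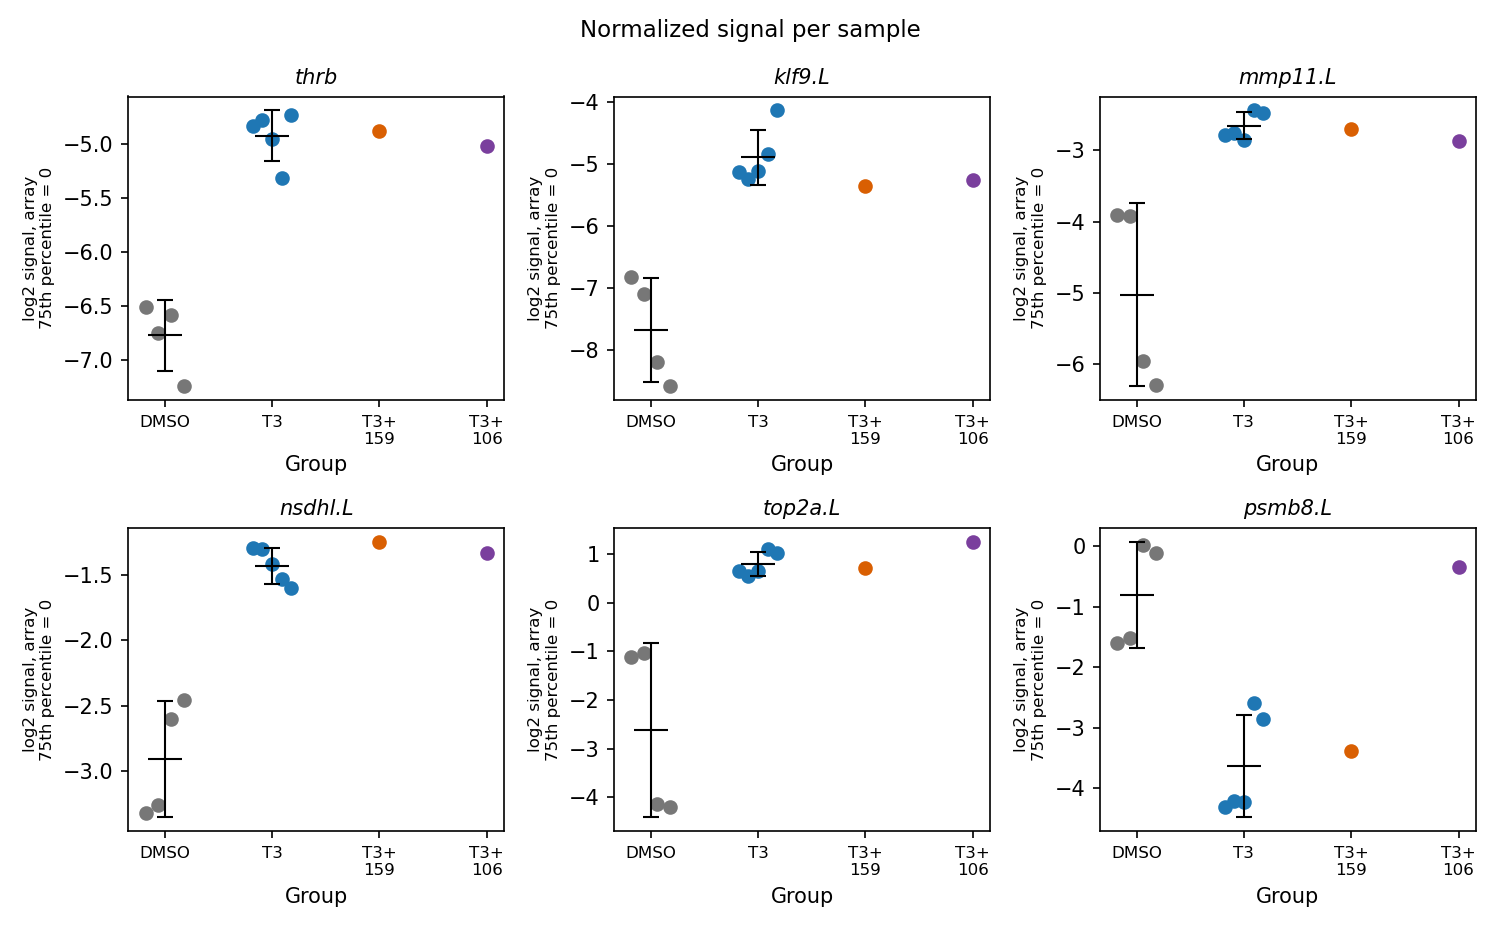
Points give the normalized log2 signal per sample (array 75th percentile = 0) of 6 genes in 4 DMSO, 5 T3, 1 T3+4OHPCB159 and 1 T3+4OHPCB106 samples, with bars for the mean and SD of DMSO and T3. The receptor gene thrb lies at -6.77 on average in DMSO and -4.92 in T3, top2a.L spreads with an SD of 1.79 in DMSO, and psmb8.L lies at -3.64 in T3 on average but at -0.348 in the T3+4OHPCB106 sample.

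Few transcripts passed between the T3+4OHPCB159 sample and T3. With 1 sample, the SE and p rest on the spread of the DMSO and T3 samples, assumed to hold here too. The carboxypeptidase gene cpo.1.L rose by 2.53 (SE 0.248, adjusted p = 0.0134 by limma, n = 1 T3+4OHPCB159 and 5 T3 samples), and the prothrombin gene f2.S rose by 1.09 (SE 0.142, adjusted p = 0.0418). The serine protease inhibitor serpina3k.L was at least 2.66-fold higher and the globin hbb2-A at least 1.13-fold higher, both below background in T3; hbb2-A was well above background on 1 of 3 arrays with 4OHPCB159. The membrane protein gene tmem45b.S passed (adjusted p = 0.0134) but was below background in both groups, and the midbrain and hindbrain transcription factor en2.L fell by 1.14 (SE 0.155, adjusted p = 0.0448). Against the T3 sample of the same slide the differences were 2.54 for cpo.1.L, 1.11 for f2.S, 2.72 for serpina3k.L and -0.928 for en2.L. With slide as a fixed block cpo.1.L alone of these 6 genes passed (adjusted p = 0.021), as with normexp or with eBayes trend and robust settings, whereas all 6 passed with slide as a random block (highest adjusted p = 0.0339).

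In all, 9 probes rose and 1 fell with 4OHPCB159, against 219 and 210 when every array was counted as a sample, and 12 and 0 with normexp. The limma count at an unadjusted p under 0.05 was 294, and simulated set differences alone gave 133 calls, above the 10 seen. Leaving out T3 replicate 3 left 5 calls, and leaving out T3 replicate 2, 4 or 5 or DMSO replicate 2 left 6 each. The always-named genes did not pass: thrb differed by 0.0437 (95% interval -0.601 to 0.688), klf9.L by -0.472 (-1.91 to 0.965), mmp11.L by -0.0451 (-1.92 to 1.83) and dio3.S by 0.139 (-0.391 to 0.67). Of the 27 lists, immediate early genes passed camera (adjusted p = 2.91e-05, adjusted p = 0.356 with an estimated correlation). Their median was 0.121 (0.188 within slide 2), 16 of 20 were higher, and 0 passed on their own by limma, 1 when adjusted over the list alone and 6 at an unadjusted p under 0.05.

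Genes that passed between the T3+4OHPCB106 sample and T3 included some that are abundant in liver. In a liver list made afterwards 6 of 24 tested members rose, and 2 with 4OHPCB159. Over the 14 detected in T3 the medians were 0.54 and 0.654. The plasma protein gene ambp.L rose by 4.85 (SE 0.815, adjusted p = 0.0399 by limma, n = 1 T3+4OHPCB106 and 5 T3 samples, with the same assumption on spread), and was well above background on 3 of 6 T3 arrays. Genes below background in T3 were higher by at least 13.1-fold for the aminotransferase agxt.L, 6.67-fold for the fibrinogen chain fga.S, 2.26-fold for the gluconeogenic enzyme pck1.S, 1.6-fold for gckr.L and 1.42-fold for the vitamin D binding protein gc.S. The dioxygenase gene hpd-like.2.L rose by 1.80 (SE 0.215), and the interferon-induced gene parp9.L by 2.52 (SE 0.377). The globin hbb2-A and tmem45b.S were at least 1.28-fold and 1.72-fold higher, and gc.S and hbb2-A were well above background on 2 of 3 arrays with 4OHPCB106. Genes that fell included dbndd1.L (fell by 3.57, SE 0.573), c5orf22.L (fell by 1.77, SE 0.213), mpv17l.S (fell by 1.30, SE 0.209), fnbp1l.S (fell by 1.24, SE 0.195), nipsnap1.L (fell by 1.20, SE 0.195), rdh5.S (fell by 1.13, SE 0.158) and the chromatin subunit kansl2.S (fell by 1.08, SE 0.0976). The chromatin gene gatad2a.L, the protease furin.S and the proton pump ATP4A were below background with 4OHPCB106 and at least 4.13-fold, 2.44-fold and 2.08-fold lower. With slide as a random block limma ended the calls of ambp.L (adjusted p = 0.0948), agxt.L (0.0812), fga.S (0.0648), gc.S (0.085), gckr.L (0.067), mpv17l.S (0.067), nipsnap1.L (0.104) and ATP4A (0.103). Of the genes named here only pck1.S, hpd-like.2.L and kansl2.S kept theirs in each setting that tested them but the averaging to 6 sets.

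By camera, 6 groups shifted together against other genes, of which 1, the myelin list, also passed with an estimated correlation. In the myelin list 12 of 13 members were lower, and 1 fell by limma, also over the list alone, a call lost with slide as a random block. The median was -0.526 (-0.334 with normexp; adjusted p = 2.56e-05, adjusted p = 0.0443 with an estimated correlation). Of the immune genes 13 of 15 were higher (median 0.879, 0.417 with normexp, adjusted p = 1.84e-05, adjusted p = 0.596 with an estimated correlation), of which 0 passed on their own by limma, 4 when adjusted over the list alone and 7 at an unadjusted p under 0.05. In the interferon and acute phase list 12 of 15 were higher, fga.S rose, and 9 rose and 1 fell over the list alone (median 0.903, 0.538 with normexp, adjusted p = 1.84e-05, adjusted p = 0.241 with an estimated correlation). The list holds the liver products fga.S, fgb.L, fgg.L and serpina1.L, and gbp1.L and tf.L in it were lower without passing. Cell cycle genes were higher in 69 of 78 cases (median 0.272, adjusted p = 0.00167), muscle genes lower in all 12 (median -0.428, adjusted p = 0.00193), and developmental signalling genes lower in 41 of 62 (median -0.0883, adjusted p = 0.0259). With an estimated correlation the adjusted p of these 3 were 0.825, 0.122 and 0.694. With normexp the muscle median was -0.0661 and the call was lost (adjusted p = 0.126). The developmental signalling call was lost with quantile normalization (adjusted p = 0.0618) and with normexp (-0.0435, adjusted p = 0.123). In these 3 lists 0 members passed by limma; 3, 2 and 9 did at an unadjusted p under 0.05, and 0, 0 and 2 over the list alone.

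In all, 33 probes rose and 25 fell with 4OHPCB106 (40 and 16 with normexp), against 1051 and 1311 when every array was counted as a sample. The limma count at an unadjusted p under 0.05 was 1065, and simulated set differences alone gave 124.5 calls, above the 58 seen. Leaving out T3 replicate 1, 2 or 3 left 18, 25 or 21 calls. The always-named genes did not pass: thrb differed by -0.0981 (95% interval -0.743 to 0.547), klf9.L by -0.371 (-1.81 to 1.07), mmp11.L by -0.215 (-2.09 to 1.66) and dio3.S by -0.48 (-1.01 to 0.0507). The 3 arrays lay alone on slide 5, so slide and compound cannot be told apart here. The T3 sets also differed in some cell cycle genes. In T3 1 to 3, mcm7.S lay at 0.065 to 0.22, and at 0.686 in T3 4 and 0.574 in T3 5 and 6. It lay at 0.665 with 4OHPCB106 and 0.267 with 4OHPCB159. By contrast, top2a.L lay at 1.258 with 4OHPCB106, above every T3 sample (0.547 to 1.111). A compound effect on cell cycle genes, against T3 or between the compounds, therefore cannot be told apart from a set difference.

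The compounds, both hydroxylated biphenyls given at 500 nM for 4 days, were compared with 1 sample each, so the differences have no replicate check and their SE and p rest on the spread of the DMSO and T3 samples. By that test the interferon-induced gene nmi.L was higher with 4OHPCB106 than with 4OHPCB159 by 1.89 (SE 0.18, adjusted p = 0.00962 by limma, n = 1 sample each), cpo.1.L was lower (difference -3.31, SE 0.321, adjusted p = 0.00962), and kansl2.S was lower (difference -1.11, SE 0.126, adjusted p = 0.0184). Further genes did not pass: parp9.L differed by 2.83 (SE 0.487, adjusted p = 0.111), gbp7.S by 2.02 (SE 0.345), pycard.L by 1.77 (SE 0.241, adjusted p = 0.0534) and mpv17l.S by -1.69 (SE 0.27). The gene pck1.S was at least 2.45-fold higher with 4OHPCB106 (adjusted p = 0.0583), and serpina3k.L, the calcium pump atp2a1.S and furin.S were at least 3.02-fold, 3.39-fold and 2.66-fold lower, without passing. The genes thrb (95% interval -0.974 to 0.691), klf9.L (-1.75 to 1.96), mmp11.L (-2.59 to 2.25) and dio3.S (-1.3 to 0.0656) did not pass, and these intervals leave room for differences of over 1.5-fold.

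By camera, immune (median 1.11, 13 of 15 higher, adjusted p = 4.07e-05), cell cycle (0.307, 69 of 78 higher, 0.00804) and interferon and acute phase genes (0.689, 9 of 15 higher, 0.0243) were higher with 4OHPCB106 than with 4OHPCB159, calls lost with an estimated correlation (adjusted p = 0.607, 0.769 and 0.716). Myelin (median -0.348, 12 of 13 lower, adjusted p = 0.000568), muscle (-0.441, 10 of 12 lower, 0.000568) and extracellular matrix genes (-0.334, 22 of 25 lower, 0.0356) were lower, calls also lost with an estimated correlation (adjusted p = 0.0621, 0.0621 and 0.716). The extracellular matrix call also ended without T3+4OHPCB106 replicate 2 (adjusted p = 0.0544). With normexp the interferon and acute phase call was lost (0.241, adjusted p = 0.0916), and the medians were 0.57 for immune, -0.225 for myelin, -0.173 for muscle and -0.172 for extracellular matrix genes. In the 6 lists 0 members passed alone by limma. At an unadjusted p under 0.05 they were 5, 5, 6, 4, 2 and 1 in that order. Adjusted over the list alone, 3 immune genes rose, 5 interferon and acute phase genes rose and 1 fell, 1 myelin and 2 muscle genes fell. In all, 3 probes were higher and 3 lower (4 and 2 with quantile normalization, 9 and 5 with normexp), against 923 and 1087 when every array was counted as a sample. The limma count at an unadjusted p under 0.05 was 699, and simulated set differences alone gave 66.5 calls, above the 6 seen. Leaving out DMSO replicate 5 gave 15 calls, T3+4OHPCB159 replicate 3 or T3+4OHPCB106 replicate 1 gave 12, DMSO replicate 1 or T3+4OHPCB159 replicate 2 gave 10, and DMSO replicate 3 left 3.

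Over the probes that T3 changed, the median differences between either compound sample and T3 were small, and the tests on merged samples could not pass. For the mean of the thyroid hormone response list the interval with 4OHPCB106 reached -0.461, where the whole T3 effect was 0.456, so a large loss is not excluded. Over the 4245 probes past the threshold for T3, the median of compound minus T3, signed by the T3 direction, was -0.0151 with 4OHPCB159 (permutation p = 1) and 0.0294 with 4OHPCB106 (permutation p = 0.167), since the 6 relabellings cannot give a p under 0.167. The value for 4OHPCB106 lay above the other 5, which ran from -0.0477 to -0.0189, and that for 4OHPCB159 within its others. With 84 relabellings of single arrays the medians were -0.016 (permutation p = 0.821) and 0.0252 (permutation p = 0.119). No p from 84 relabellings can be under 0.0119. Counting single arrays treats compound arrays that differ by less than spot noise as independent. When the T3 samples used for selection were kept out of the comparison, T3-induced probes differed by a median of -0.026 with 4OHPCB159 and 0.0691 with 4OHPCB106, and T3-repressed probes by -0.00155 and -0.0284, with no test. The mean of the thyroid hormone response list differed from T3 by 0.0409 with 4OHPCB159 (95% interval -0.285 to 0.366; 0.0364 within slide 2; exact permutation p = 0.333, adjusted p = 0.4). It differed by -0.135 with 4OHPCB106 (-0.461 to 0.19; exact permutation p = 0.167, adjusted p = 0.333; exact permutation p = 0.0119 with every array a sample), and by -0.176 between the compounds (-0.596 to 0.244).

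Against DMSO, genes of the T3 response also rose in both compound samples. The receptor thrb rose by 1.89 with T3 and 4OHPCB159 (SE 0.291, adjusted p = 0.00892 by limma, n = 1 and 4 samples) and by 1.75 with T3 and 4OHPCB106 (SE 0.291, adjusted p = 0.00627). With slide as a fixed block the first call ended (adjusted p = 0.0574), and with a random block it passed (adjusted p = 0.00646). The factor klf9.L was at least 2.34-fold (adjusted p = 0.0524) and 2.51-fold higher (adjusted p = 0.0317, and 0.0668 with slide as a random block). The protease mmp11.L differed by 2.32 (adjusted p = 0.105) and 2.15 (adjusted p = 0.102), and dio3.S by 0.195 and -0.424, without passing. Of 78 cell cycle genes 29 rose with T3 and 4OHPCB159 (62 over the list alone; median 1.58, 0.7 with normexp), and 58 with T3 and 4OHPCB106 (67 over the list alone; median 1.97, 1.05 with normexp). Camera passed 8 lists with 4OHPCB159, namely cell cycle, sterol, heat shock, respiratory chain and proteasome upward and immune, myelin and ribosome downward. It passed 9 with 4OHPCB106, the same list names less immune and with muscle and epithelium downward, and 0 of either passed with an estimated correlation (lowest adjusted p = 0.452 and 0.12). With 4OHPCB106, quantile normalization ended the calls of muscle (adjusted p = 0.136), ribosome (median -0.0551, adjusted p = 0.409) and epithelium (adjusted p = 0.0595), and normexp those of muscle (adjusted p = 0.252) and ribosome (adjusted p = 0.355). Muscle was also lost with every array a sample (adjusted p = 0.0571) and without DMSO replicate 1 (adjusted p = 0.0531). In all, 4OHPCB159 with T3 gave 523 probes up and 582 down (2635 and 2995 with every array a sample; 334 in all with slide as a block). They came to 634 without T3 replicate 1, 644 without DMSO replicate 3 and 697 without T3 replicate 2 or 3. With 4OHPCB106 there were 1022 up and 1066 down (2717 and 3446 with every array a sample), with no slide shared with DMSO.

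**Figure D3:**
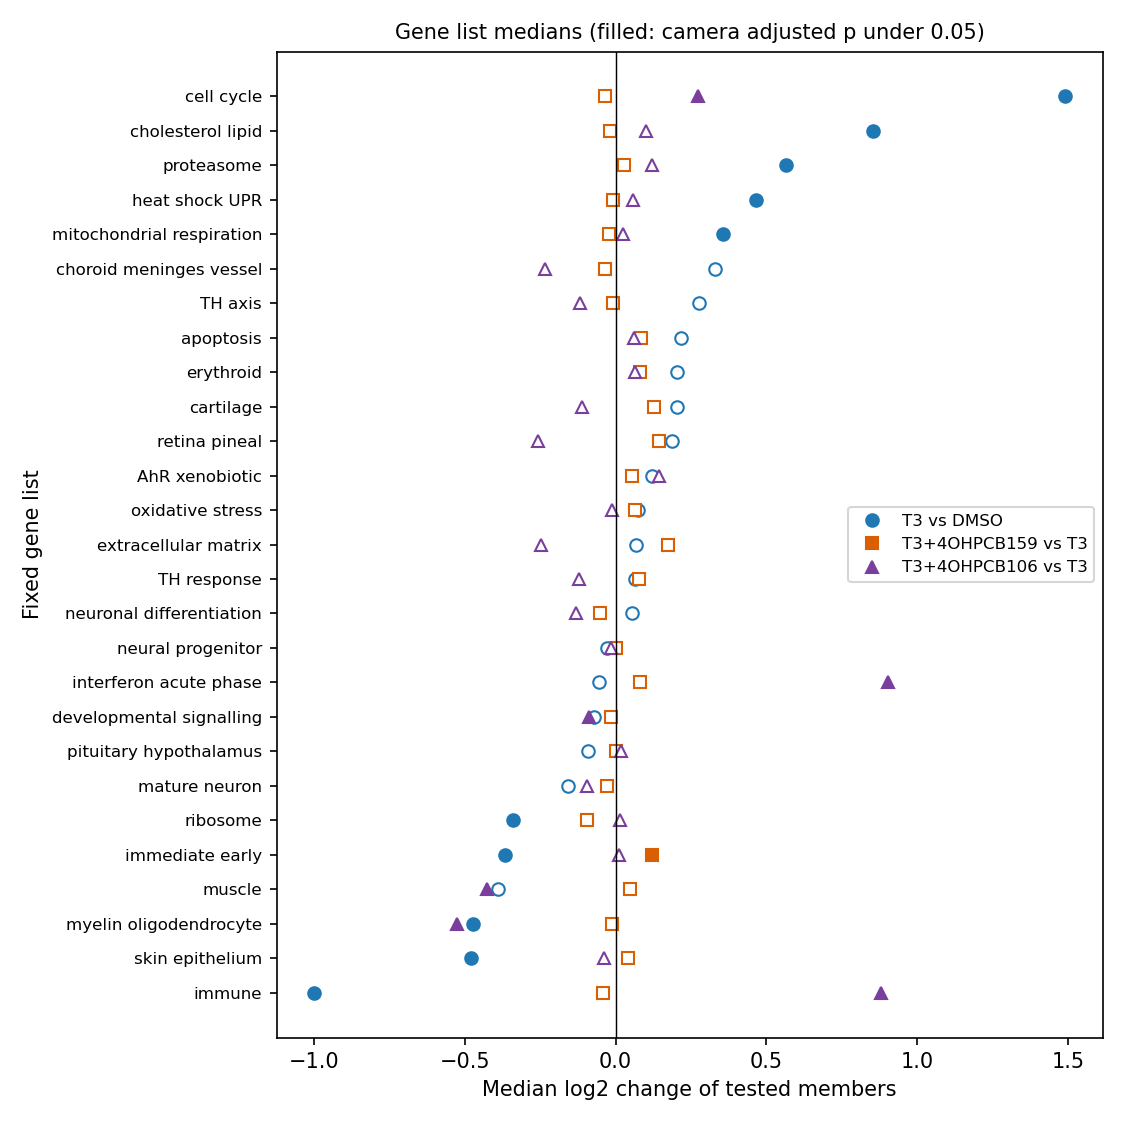
The horizontal axis gives the median log2 change of the tested members of each fixed gene list on the vertical axis, for T3 against DMSO and for each compound with T3 against T3, with filled points where camera's adjusted p was under 0.05. Cell cycle genes lie at 1.49 for T3 against DMSO and at 0.272 for T3+4OHPCB106 against T3, and immune genes lie at -1 and 0.879.

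The differences of both compounds from T3 correlated across the 10507 probes at r = 0.173, where genes are not independent replicates, and simulated unchanged groups that shared the T3 samples gave r = 0.163. The covariance was 0.0277, against 0.0264 in the simulation. With the T3 samples divided between the compounds, r had a median of 0.0866 and ran from -0.222 to 0.185 over 10 divisions.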

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

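The tests of slide mixing, signal compression, normalization, liver RNA, MHC haplotype, slide and a weaker T3 response were all chosen after the results were seen, and the split of the samples was chosen before. The bounds for slide mixing, liver RNA, MHC haplotype, the slide of the T3+4OHPCB159 sample and a weaker T3 response were also rewritten after values were seen. Under the bound first used for the haplotype, put on the 7 genes outside the fixed lists that had not been looked at, it would stay open for the fall too. A weaker response was first argued against by the cell cycle median (0.272), then left open when an estimated correlation was asked for.

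The number of probes that T3 changed is larger than other splits of the 9 samples gave, which treat as independent samples that form 4 sets. Of 100 drawn splits of the 9 samples into 5 and 4 (126 are possible), only the real one gave as many as 4245. The highest of the others drawn gave 6. Slides 3 and 4 against slides 1 and 2 is also a split into 5 and 4, was not among those drawn, and gave 976. Over all 126 splits the highest other count is therefore at least 976. The split of slide 1 against the rest gave 3. The T3 change also differed between slide 1 and slide 3 for 2077 probes by limma (3926 at an unadjusted p under 0.05, 7 samples). Simulated set differences of the size between the T3 sets gave 601.5 calls, and averages of the sets gave 0 by limma (1905 at an unadjusted p under 0.05). The real split gave more calls than any other split counted, which does not exclude differences between sets.

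The T3 response was smaller on slide 1 than on slide 3: among probes with a mean change of at least 1, the median was 1.03 against 1.73 for the 553 raised and -1.09 against -1.5 for the 440 lowered. The spike-in slope was higher on slide 1 by 0.033, which argues against signal compression there, and the cell cycle median kept a slide ratio of 0.573 with quantile normalization (0.521 without), which argues against the normalization. T3 RNA mixed into DMSO 1 and 2 may be a candidate cause: a share of 26.8% would account for the raised probes and predicts -1.22 for the lowered ones, where equal scaling predicts -0.893. The observed -1.09 lies between and cannot decide. Mixing would not account for genes that changed more on slide 1. One is Gh, at 1.205 and 1.241 in DMSO 1 and 2, farther from its T3 values than 0.525 in DMSO 3 and 0.35 in DMSO 4 and 5. The prediction also takes the T3 samples of slides 1 and 3 as alike, although the T3 sets differed (ratios of 10.3 to 18.4 to spot noise). That prediction was rewritten after values were seen: a first version with a wider margin would have read in favour of mixing, and a version based on probes above a ceiling was dropped because they lie near background, while a difference between batches of tadpoles was not tested.

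Liver-type transcripts were higher in both compound samples than in T3. Over 24 tested members of a liver list, made after such genes had been seen, the median was 1.27 with 4OHPCB159 and 2.05 with 4OHPCB106, but 10 of them were below background in T3, where differences are not exact, and over the 14 detected there it was 0.654 (quartiles -0.181 to 2.48) and 0.54 (-0.00281 to 2.63). For 4OHPCB159, a difference within slide 2 cannot come from a difference between slides. Against the single T3 sample there it was 1.21 over the list and 0.639 over the 14 detected in T3. It was 0.227 over the 9 members outside the fixed lists and not named above. How far slide adds to the 1.27 is therefore not decided. The 2.05 for 4OHPCB106 comes with slide 5, so a slide effect cannot be told apart there. Liver RNA carried over at dissection is a candidate cause that stays open. The same 9 members had medians of 0.432 with 4OHPCB159 (quartiles -0.182 to 1.86) and 0.757 with 4OHPCB106 (0.354 to 2.53). The 7 of them not looked at when the list was made had the same medians (quartiles -0.0897 to 1.77 and 0.116 to 2.26). Only 5 of the 9 were detected in T3, and the others passed the filter through other groups, so neither median is free of selection. Of these 5, rbp4.L differed by 1.86 and 2.66, hpd.L by -0.182 and -0.122, ahsg.L by -0.28 and 0.541, serpind1.L by 0.00301 and -0.282, and f10.L by -0.364 and 0.354. An effect of the compounds on these genes in brain also stays open and was not tested.

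Interferon and antigen-processing genes were lower with T3 than with DMSO and higher in the T3+4OHPCB106 sample than with T3. Some of them also differed between the sets of a group. In T3 1 to 3, psmb8.L lay at -4.318 to -4.211, but at -2.586 in T3 4 and -2.851 in T3 5 and 6. With 4OHPCB106, cfb.L lay at -0.046, near T3 4 (-0.167) and T3 5 and 6 (-0.145). In contrast, irf1.L lay at -3.42 to -3.3 in all T3 samples and at -2.704 with 4OHPCB106. Set differences were not tested as a cause here. A different MHC haplotype in the T3 tadpoles should spare interferon-induced genes outside the MHC. The 6 of these in the fixed lists had a median of -0.753 with T3 (quartiles -1.04 to -0.368). Of random lists 0.25% lay lower, and 4 of the 6 fell by limma. The 8 others not named above gave -0.69 (quartiles -1.05 to -0.0485). Without dhx58.L, looked at earlier, the other 7 gave -0.664 (quartiles -0.871 to 0.0891). By the bound as rewritten, these values argue against the haplotype as the whole cause of the fall. Among the 6, however, irf8.L, irf1.L and irf1.S had been named above for falling, so the 6 are no independent test. The quartiles of the 7 span 0, so the haplotype is not excluded for the fall. For the rise with 4OHPCB106 all 18 gave 0.744 (quartiles 0.195 to 1.4), but that list held genes chosen for rising. The 6 gave 0.575, the 8 others 0.226 (-0.168 to 1.13) and the 7 without dhx58.L 0.164, which leaves the haplotype open. A slide effect cannot be told apart from the rise, because slide 5 held that group alone. The rise was 1.85 over 7 genes listed as MHC-linked. That list holds cd74.L, the invariant chain gene, which lies outside the MHC and differed by 0.879. A weaker T3 response as a whole that undid 87.9% of the immune fall would need a shift of -0.53 over the 4245 probes, and the 0.0294 seen, beside -0.0477 to -0.0189 for relabelled T3 samples, argues against that cause, although the thyroid hormone response mean differed by -0.135 (95% interval -0.461 to 0.19), while an action of 4OHPCB106 on these genes stays open, untested.

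Single samples stood apart from the rest of their group in 10 of 308 group values tested (3.25%), and chance flags about 1 in 20 groups. The gap to the nearest sample over the range was 0.86 for fap.L (DMSO 1), 0.855 for nkx2-2.S, 0.933 for gclm.L and 0.843 for uqcrc1.L (DMSO 3). In T3 it was 0.848 for ncam1.L (T3 5 and 6), 0.733 for irf1.L (T3 2), and 0.806 for pcsk2.L, 0.792 for nr4a1.S, 0.814 for rps10 and 0.858 for psmc1.L (T3 4).

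The effects of the compounds against T3 differed by limma for nmi.L (1.887), cpo.1.L (-3.306) and kansl2.S (-1.105), 4OHPCB106 minus 4OHPCB159, with 1 sample each and no replicate check. By camera they differed for the lists of immune (1.11), interferon and acute phase (0.689), cell cycle (0.307), myelin (-0.348), muscle (-0.441) and extracellular matrix genes (-0.334), of which none passed with an estimated correlation (lowest adjusted p = 0.0621).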

How the results depend on the processing

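Each array as a sample, averaged sets, the percentile over all probes, fits within slide 1 or slide 3 and fits without DMSO 1 and 2 were chosen after seeing the data; the other settings were fixed before. Averaging arrays that differed by less than spot noise was itself a step taken after the 17-array counts had been seen.

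With every array a sample, 6081 probes passed for T3 against DMSO, 429 for 4OHPCB159 against T3, 2362 for 4OHPCB106 against T3, 2010 between the compounds, 5630 for 4OHPCB159 against DMSO and 6163 for 4OHPCB106 against DMSO, since more samples are counted. With the arrays averaged to 6 sets, limma gave 0 probes for each of the 6 comparisons, with 1905, 109, 475, 418, 1367 and 1900 at an unadjusted p under 0.05, since fewer samples are counted. Below, the cause was not tested.

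Same-numbered arrays of T3 and DMSO gave 4 of 5 correlations over 0.1 (from -0.116 to 0.475), and the other pairs of groups 0 or 1 of 3. Some of the same-numbered T3 and DMSO arrays also share a slide, so whether the numbers pair the samples stays open. The main fit did not pair them. With every array a sample and the replicate block the counts were 6386, 290, 2806, 2515, 5428 and 6264 in the same order, and the T3 against DMSO score was 0.509 (exact permutation p = 0.0625, the smallest that 5 pairs can give, so it could not pass).

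For T3 against DMSO, asking also for a fold of 1.5 left 2193. For 4OHPCB159 against T3 the count was 1 with probes well above background on all arrays, 1 with eBayes trend and robust settings, 4 and 19 with slide as a fixed and random block, 18 at an adjusted p under 0.10, 21 without DMSO 1 and 2, and 6 with only the 2 groups compared. For 4OHPCB106 against T3 it was 38 with no filter, 35 with slide as a random block, 96 at 0.10 and 168 without DMSO 1 and 2. Between the compounds it was 14 with normexp, 11 with slide as a random block, 21 at 0.10 and 62 without DMSO 1 and 2. For 4OHPCB159 against DMSO it was 333 with no filter, 334 with slide as a fixed block, 2200 at 0.10, 3311 without DMSO 1 and 2, and 48 with only the 2 groups compared. For 4OHPCB106 against DMSO it was 1159 with no filter, 3194 at 0.10, 3675 without DMSO 1 and 2, and 185 with only the 2 groups compared.

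Of 40 list calls over the 6 comparisons, 1 held with an estimated correlation, and 3 lists passed with every array a sample and an estimated correlation. With fry, which asks whether a list changed rather than whether it changed more than other genes, 9 of the 40 did not pass. Another 13 list calls were gained with fry. The sign of no called list median flipped under 5 scalings, and the largest move was 0.92, with normexp. With every array a sample the thyroid hormone response score had an unadjusted p under 0.05 in 3 comparisons of the compounds. These were 4OHPCB106 against T3 (-0.141, exact permutation p = 0.0119), 4OHPCB159 against DMSO (0.541, exact permutation p = 0.0179) and 4OHPCB106 against DMSO (0.365, exact permutation p = 0.0357). The p of 0.0119 is the smallest that 84 relabellings can give. The 3 arrays of a compound group differed by less than spot noise, so these p-values count 1 sample as 3. Of 6019 values of named genes over all settings and comparisons, 435 lost their call, 63 gained one and 0 reversed; with the arrays averaged to 6 sets 125 of the 126 T3 against DMSO values lost it.

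Leaving out each array in turn gave 3380 to 4254 probes for T3 against DMSO, 5 to 11 for 4OHPCB159 against T3, 18 to 63 for 4OHPCB106 against T3, 3 to 15 between the compounds, 634 to 1413 for 4OHPCB159 against DMSO and 1594 to 2214 for 4OHPCB106 against DMSO. List calls ran from 39 to 42, the shifts from -0.0279 to -0.00829 and from 0.016 to 0.0391, and the score of T3 against DMSO from 0.431 to 0.53. Dim probes limit the rest: a probe below background on all arrays of a group has only a bound there.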

Other observations

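The tests on marker lists below were chosen after the results were seen, and the 27 fixed lists before.

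Further groups held genes that changed with T3 by limma without passing camera as lists. Heme synthesis genes urod.S (1.12) and fech.L (0.91, not past with slide as a block, adjusted p = 0.0652; well above background on 1 of 5 DMSO arrays) rose, as did col2a1 of cartilage (1.18), the lens crystallin gene cryba4.S (1.69) and the antioxidant gene gpx7.L (1.22). The autophagy receptor sqstm1.L fell by 1.17, and the cone opsin gene opn1lw.L was at least 2.14-fold lower and below background in T3. The vascular receptor flt1.L was at least 1.92-fold and the cell cycle inhibitor cdkn1a.L at least 2.09-fold higher, both below background in DMSO. Among xenobiotic genes por.L rose by 0.51, nqo1.L fell by 0.66, and aldh3b1.L was at least 1.46-fold lower.

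Of the lists not yet given in full for T3 against DMSO, 5 of 19 thyroid axis genes rose and 2 fell (median 0.275), 7 of 21 xenobiotic genes rose and 4 fell (0.121), 8 of 27 oxidative stress genes rose and 5 fell (0.0752), and 6 of 13 apoptosis genes rose and 4 fell (0.216). Of 15 choroid plexus, meninges and vessel genes 5 rose and 2 fell (0.331), of 25 extracellular matrix genes 6 rose and 5 fell (0.068), and of 62 developmental signalling genes 10 rose and 12 fell (-0.0715). Of 15 pituitary and hypothalamus genes 1 rose and 3 fell (-0.0918), of 7 cartilage genes 3 rose and 2 fell (0.203), of 6 red cell genes 2 rose and 0 fell by limma (0.203), of 12 muscle genes 1 rose and 3 fell (-0.391), and of 15 retina and pineal genes 2 rose and 3 fell (0.186). Camera gave no adjusted p under 0.05 for these 12 lists.

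For xenobiotic genes, a list fixed for compounds of this kind, the median was 0.145 for 4OHPCB106 against T3 (camera adjusted p = 0.229).

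Interferon-induced genes outside the MHC had a median of -0.247 with 4OHPCB159 against T3 over 18 members (quartiles -0.478 to -0.12; 0.02% of random lists lay lower), and -0.336 within slide 2. The 8 of these neither in the fixed lists nor named gave -0.234 (0.76% of random lists lay lower) and -0.358 within slide 2. Without dhx58.L, which had been looked at earlier, the other 7 gave -0.116 (12.6% lower) and -0.0873. With T3 against DMSO the liver list had a median of -0.121 over 24 members.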
